A study of Mus musculus with 5 samples.

How the data were processed

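Chromatin immunoprecipitation with sequencing (ChIP-seq) for SIRT7 was done in female mouse TTF cells that carry a C57BL6 and a CAST genome; the labels do not spell out TTF. Per the labels' protocols, crosslinking took 10 min in 1% formaldehyde, chromatin was sheared to 300 to 500 bp, and 1% of it was kept as input. The labels gave 5 libraries in 4 groups: 2 ChIP libraries of wild-type (WT) cells, 1 ChIP library of SIRT7-knockout (KO) cells, 1 WT input and 1 KO input. The labels do not say whether the WT libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

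The deposited counts are whole reads per 1 Mb bin, and each library has 4 count columns: all reads, reads of genome1, reads of genome2 and unassigned reads. Per the submitters' processing notes, FastQC 0.11.3, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19 and the mm10 build were used. How reads were assigned to a genome is not given in the sources used here, nor is which of genome1 and genome2 is C57BL6. A second deposited table holds a ratio per bin. Each finite ratio equalled the ChIP count divided by the input count of the same genotype and allele class, to a tolerance of 1e-09, with no factor for sequencing depth, as checked on the files. The counts were therefore used for every test.

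Total reads were 174003957 and 167007601 in the WT ChIP libraries, 4968189 in the KO ChIP library, and 224205689 and 219168466 in the WT and KO inputs. The median tested bin held 60744 and 57952 reads in the WT ChIP libraries, 1773 in the KO ChIP library, 77046 in the WT input and 79519 in the KO input. The median counting error of the KO log2(ChIP/input) of a bin was 0.035. Intervals of shares are 95% intervals that cover counting error only, since duplicate reads cannot be told from separate molecules. The WT ChIP libraries differed by more than counting noise, with a median chi-square per bin of 4.22 against 0.455 for counting alone, and were kept as 2 libraries.

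Counts were fitted with edgeR 4.0.16 (R 4.3.3; quasi-likelihood, TMM scaling, 4 group means) on the 2582 bins of the 19 autosomes and X with a mean of at least 100 reads, of which 168 were on X. Benjamini-Hochberg adjusted p-values were held against 0.05. The fit has 1 residual degree of freedom, from the WT ChIP pair, and the single libraries were assumed to vary like that pair. The dispersion that edgeR fitted lay under 1e-04 for 2513 bins, with a median of 9.77e-05. There the deviance returned by edgeR had a median of 92.4, whereas the same deviance computed directly from its formula had a median of 0.466, and 111 test statistics over the 5 comparisons were negative. The dispersion was therefore raised to a floor of 1e-04, where both calculations gave 0.456. This floor was set after the calls had been seen and it changed them: with no floor the counts of called bins were 2081, 368, 0, 2 and 2097 for the 5 comparisons, and with the floor 1938, 1297, 73, 1651 and 1983. Floors 1.01, 1.1 and 2 times as high were also run after the calls had been seen. They gave 82, 115 and 279 bins for WT minus KO, 1303, 1337 and 1479 for KO over input, and 1653, 1685 and 1750 for WT ChIP over KO ChIP. WT over input stayed at 1934 to 1938 and the inputs at 1977 to 1983. A quasi-Poisson fit was added as well. The same floor was used in the allelic fit, which had library as a block.

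Descriptive values are log2 of the TMM-scaled counts (CPM) plus a pseudocount of 1, ChIP minus the input of the same genotype. Medians over X and over fixed lists were set against 10000 random lists of the same size. Chromosomes and X segments were set against runs of neighbouring autosomal bins, which were not matched on count and could cross chromosome ends; other lists were matched on quintile of mean count. These percentiles describe the libraries and are not tests of genotype. Genes were placed with a RefSeq table of the same mouse build. Before the data were examined, the lists were fixed as each chromosome, X segments, bins next to centromeres and chromosome ends, nucleolus organiser chromosomes, gene-number quintiles, and bins holding imprinted loci, X escape genes, X structural loci, histone clusters, ribosomal protein genes, sirtuins, olfactory and vomeronasal receptors and protocadherins. Quintiles of GC content were not analysed here. The bins named were those 10 highest and 10 lowest among bins past 0.05 with both WT libraries on the same side, for WT ChIP over input and for WT minus KO; the 3 highest and 3 lowest in the other fits; the bins of Xist, Firre, 4933407K13Rik and Sirt7; and the X bins highest and lowest in WT minus KO. Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom), other scalings, count minimums, pseudocounts, bins without extreme input and each WT ChIP library left out.

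The fit with the floor was tested on simulated counts for the 2582 bins, 200 of which were changed. For WT ChIP over input, 96% of bins seeded with a log2 change of 0.1 were called, and 100% of those seeded with 0.2. For WT minus KO, 8% were called at 0.1, 84% at 0.2 and 100% at 0.4, and 0.042% of unchanged bins were called. The simulation assumed that all groups share 1 spread, which these libraries cannot check. Its counts were drawn with the dispersion fitted here, raised to the same floor, so it cannot check the floor. Figures and summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.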

Results

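SIRT7, a sirtuin deacetylase found largely in the nucleolus, was profiled by ChIP-seq in WT and SIRT7-KO hybrid mouse cells, with 2 WT ChIP libraries, 1 KO ChIP library and 1 input of each genotype. Reads were counted in 1 Mb bins of mm10. The KO ChIP library held 4968189 reads, against 174003957 and 167007601 in the WT ChIP libraries, so a KO value carries a larger counting error than a WT value. The bin that holds Sirt7 (chromosome 11, 120000001 to 121000000) had 64201 and 62094 reads in WT ChIP, 1653 in KO ChIP, 71898 in WT input and 60758 in KO input. A bin of this width holds 46 protein-coding genes and cannot show whether the gene is deleted.

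The first comparison asks where SIRT7 ChIP signal exceeded input in WT cells. Signal followed gene number. The 517 bins with most genes (median 20) had median log2(ChIP/input) of 0.090 and 0.11 in the WT libraries, and the 517 with fewest (median 0) had -0.063 and -0.082. The highest bin lay on chromosome 4 from 154000001 to 155000000, where Prdm16, a transcriptional regulator of brown fat, and Trp73, a relative of Trp53, are located; it was 1.45-fold over input (log2 0.54, SE 0.019; edgeR adjusted p 4.62e-145). Of the 10 highest bins, 5 were on chromosome 4, among them one with the Padi genes for peptidylarginine deiminases at 140000001 to 141000000, at log2 0.44. The others included the X bin 170000001 to 171000000 with Asmt, the last enzyme of melatonin synthesis, also at log2 0.44. The lowest bin was on chromosome 1 from 24000001 to 25000000, with the collagen genes Col9a1 and Col19a1, at 0.544-fold (log2 -0.88, SE 0.018). The WT libraries gave -0.94 and -0.82 there. Chromosome M held 0.0126% and 0.0297% of reads in WT ChIP, 0.0408% in KO ChIP, and 0.217% and 0.181% in the WT and KO inputs. Among ChIP libraries, both this share and this bin were lowest in WT replicate 1 and highest in KO. A link between them was not tested, so the bin's value need not concern its genes. Other low bins held few genes, such as those of the axon guidance genes Sema3a (chromosome 5, 13000001 to 14000000, log2 -0.29) and Slit2 (chromosome 5, 47000001 to 48000000, log2 -0.31).

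In WT cells 970 bins were above input and 968 below (824 and 1134 with TMM from autosomes), but most differences were small. Only 3 of these bins exceeded 0.5 on the log2 scale in either direction, and 0 exceeded 1. The 5th and 95th percentiles of all bins were 0.897-fold and 1.17-fold. Among the fixed lists, the 78 bins with ribosomal protein genes had a median 0.11 above the autosomal median. Of these, 57 were above input and 13 below, over all bins and adjusted over the list alone. Random lists were matched on mean count and not on gene number. The gene-richest quintile of bins had a median of 0.10, so high list medians were not separated from gene number. The 11 bins of imprinted loci had a median of 0.14, with 8 above and 1 below. The 7 bins of sirtuin genes had a median of 0.20, with 6 above and 0 below. The 13 protocadherin bins had a median of -0.078, with 2 above and 8 below. With summed counts the ribosomal protein list stayed set apart, but imprinted loci (0.0885), sirtuin (0.129) and protocadherin bins (-0.0615) fell inside the range of random list medians. That range is of medians over bins, a measure unlike summed counts. The first 10 counted bins of chromosomes 12, 15, 16, 18 and 19 stood for the nucleolus organiser chromosomes of C57BL6. They lay at the 85.9th percentile of matched random lists and were not set apart. Without bins of extreme input, which left chromosome 15 no bin, the list was set apart, at 0.0459. The ribosomal RNA genes themselves were not analysed here, so these bins do not show whether SIRT7 binds them. With all libraries thinned to the KO ChIP depth, 986 bins passed in place of 1938.

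A similar pattern was present in the KO ChIP library. The KO ChIP library had the highest bins on chromosome 4 at 140000001 to 141000000 and at 153000001 to 154000000 (both log2 0.51) and on X at 170000001 to 171000000 (log2 0.47, SE 0.10). Its lowest were the chromosome 1 bin with Col9a1 (log2 -0.66, SE 0.037), the chromosome 2 bin with Gad2 at 22000001 to 23000000 (log2 -0.41) and a chromosome 10 bin with 0 protein-coding genes at 16000001 to 17000000 (log2 -0.37). Across bins, which are not independent replicates, KO and mean WT log2(ChIP/input) correlated with Pearson's r of 0.868. The slope of KO on WT was 0.936, with a 95% interval of 0.901 to 0.968 from resampled chromosomes. Ribosomal protein bins had a KO median of 0.14, imprinted loci 0.15 and sirtuin bins 0.25, against 0.11 for the gene-richest quintile. Protocadherin bins had -0.060, which lay inside the random range (-0.087 to 0.084). The edgeR test called 1297 KO bins, 557 above input and 740 below, but 479 with limma-voom, 368 with no dispersion floor and 59 in a quasi-Poisson fit. Which direction held more bins depended on the setting: 651 were above and 598 below with TMM from autosomes, 596 and 498 without bins of extreme input, and 263 and 216 with limma-voom. Bins above input in both genotypes numbered 528, against 209.3 for independent lists, and bins below in both numbered 631, against 277.4.

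**Figure D1:**
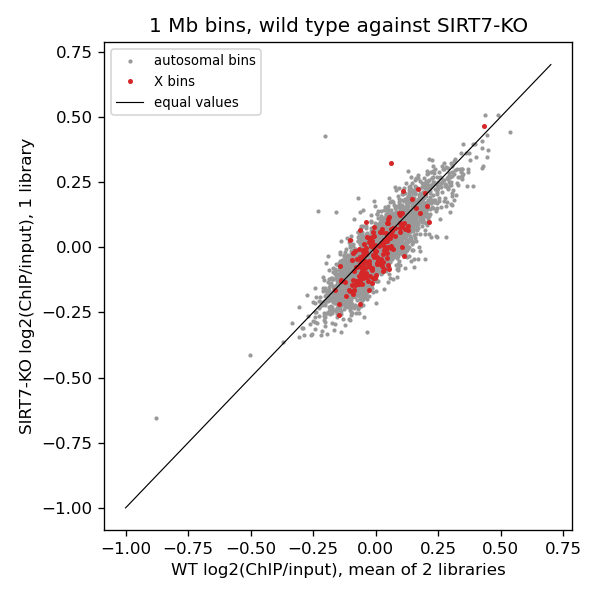
Log2(ChIP/input) per 1 Mb bin, mean of the 2 WT libraries on the horizontal axis and the single KO library on the vertical axis; each point is a bin, red on X and grey on autosomes. The bins follow the line of equal values, with r of 0.868 across bins.

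The main comparison is WT minus KO, each corrected by its own input. No count of differing bins held across tests. The edgeR test with the dispersion floor, which was set after the calls had been seen, called 73 of 2582 bins. It called 0 with edgeR's default dispersion and 0 in a quasi-Poisson fit, with 181 and 20 bins at an unadjusted p under 0.05, where chance gives 129.1. DESeq2 called 6, limma-voom 1, and a floor 2 times as high 279. The direction also depended on scaling: 63 bins were higher in WT and 10 lower with TMM, 46 and 31 with DESeq2 size factors, 12 and 6 with library totals, and 19 and 63 with TMM from autosomes. The called differences lay between 0.13 and 0.29 on the log2 scale in size. The KO side rests on 1 library of low depth, and the WT pair alone sets the spread. The counts of 0 do not show that no bin differs, since the default dispersion has the deviance error described above. The quasi-Poisson fit applies the overdispersion of deep WT libraries to the shallow KO library.

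The named bins are given as values of the edgeR fit with the floor. Higher in WT was a bin on chromosome 4 from 76000001 to 77000000 within Ptprd, a receptor phosphatase gene (log2 0.29, SE 0.047, adjusted p 9.86e-07), with WT minus KO of 0.31 and 0.27 for the WT libraries. Next came the bin of the cell adhesion gene Cadm1 (chromosome 9, 47000001 to 48000000, log2 0.25), that of Vstm2b (chromosome 7, 40000001 to 41000000, 0.24) and that of the carboxylesterase genes Ces1a to Ces1h (chromosome 8, 93000001 to 94000000, 0.23). The bin of the major urinary protein genes had 0.20 (chromosome 4, 60000001 to 61000000). Lower in WT was the chromosome 1 bin with Col9a1 (log2 -0.22, SE 0.043), for which a link with the chromosome M share was not tested. Other bins lower in WT were those of Rdx (chromosome 9, 52000001 to 53000000, -0.19), of B020011L13Rik (chromosome 1, 117000001 to 118000000, -0.18) and of Apc, the tumour suppressor of Wnt signalling (chromosome 18, 34000001 to 35000000, -0.16). DESeq2 lost the bins of Col9a1 (adjusted p 0.611), Vstm2b (0.0596), the major urinary protein genes (0.181), B020011L13Rik (0.0893) and Apc (0.102). With library totals the major urinary protein bin (0.176) and the B020011L13Rik bin (0.0734) did not pass, nor did the former with TMM from autosomes (0.078) or without bins of extreme input. The Col9a1 bin was also lost with robust dispersion estimation. With limma-voom and with thinned libraries, none of the bins named here passed.

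Of the 40 fixed lists, 8 had a WT minus KO median outside the central 95% of random lists. Ribosomal protein bins had -0.021, with 0 bins higher and 1 lower over all bins, and 0 and 0 adjusted over the list alone. The last 5 bins of chromosomes had -0.019, the gene-poorest quintile of bins 0.020, the next quintile 0.012 and the gene-richest -0.021. The chromosomes set apart were 5 (0.021), 12 (0.024) and 15 (-0.027). Relative to autosomes, log2 WT over KO input on them was -0.086, -0.193 and 0.194, each of the other sign. A difference between the single inputs was therefore not separated from these values. The size depended on the WT library: the gene-poorest quintile had 0.026 with replicate 1 and 0.011 with replicate 2, and Spearman's rho of gene number with ChIP over input was 0.437 and 0.513 in WT and 0.521 in KO. Without replicate 1, ribosomal protein bins (-0.015) and chromosome 15 (-0.022) were no longer set apart, and without replicate 2 neither was chromosome 12 (0.024), while the quintile next to the gene-richest (-0.0058) then was. With summed counts the gene-poorest quintile had 0.0026, chromosome 15 had -0.012, ribosomal protein bins -0.014 and chromosome ends -0.0007, all inside the range of random list medians. Outside that range were then chromosomes 2 (-0.043), 8 (0.024), 9 (-0.024) and 14 (-0.035) and the middle quintile (0.0074). The medians over bins had the other sign for chromosome 9 (0.0091) and the middle quintile (-0.0024). Summed counts are weighted by reads, whereas the range is of medians over bins, so these gains and losses compare unlike measures. The bin with most reads, at 98 Mb of chromosome 2, held 1.55% and 1.99% of WT ChIP reads and 2.28% of KO ChIP reads. Sirtuin bins, at -0.049 and the 4.16th percentile, were not among the 8. Without bins of extreme input, sirtuin bins (-0.0585) and chromosome 7 (-0.016) were set apart and chromosome ends (-0.0012) were not. With a pseudocount of 10 chromosome 12 (0.022) was not.

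Chromosome X did not stand apart. Its median log2(ChIP/input) differed from the autosomal median by -0.0026 and -0.021 in the WT libraries and by -0.012 in the KO library, at percentiles 47.4, 25.03 and 32.4 of random autosomal runs. X ranked 12th, 15th and 13th of 20 chromosomes. WT minus KO on X was 0.0064 and -0.0028 for the WT libraries, at the 75.4th and 45.9th percentiles. Without input, WT ChIP exceeded KO ChIP on X by 0.20, because the WT input did so as well. The bin of Xist, the RNA that coats the inactive X (103000001 to 104000000), had WT minus KO of -0.030 (SE 0.042; edgeR adjusted p 0.749). The bin of the noncoding RNA gene Firre (50000001 to 51000000) had 0.0082 (SE 0.042; edgeR adjusted p 0.938), and that of 4933407K13Rik (75000001 to 76000000) had -0.058 (SE 0.042; edgeR adjusted p 0.464). The highest X bin was 82000001 to 83000000, in the dystrophin gene Dmd (log2 0.16, SE 0.044; edgeR adjusted p 0.0234, DESeq2 0.226). The lowest was 125000001 to 126000000 (log2 -0.27, SE 0.14; edgeR adjusted p 0.274). The Dmd bin did not pass with DESeq2, library totals, TMM from autosomes (log2 0.12) or limma-voom. The 6 bins of X escape genes had a WT minus KO median of 0.019, and 0 of them passed.

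**Figure D2:**
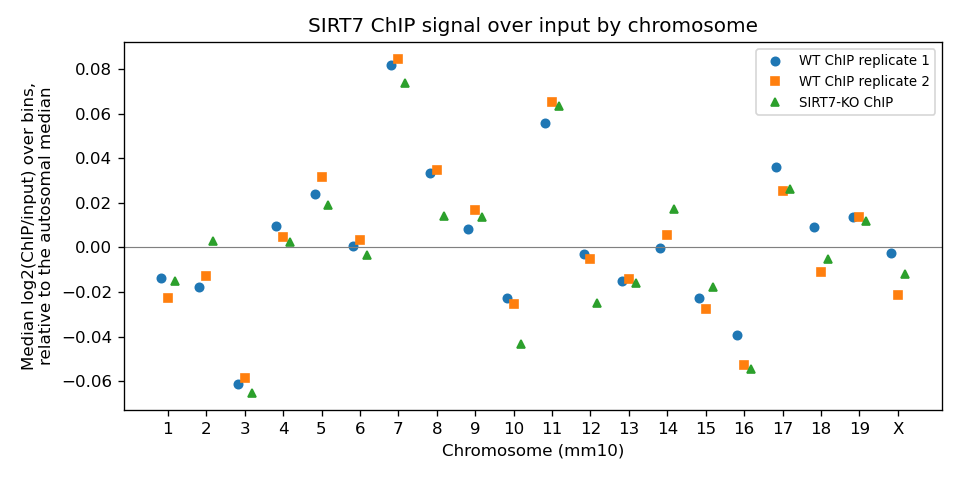
Median log2(ChIP/input) over the bins of each mm10 chromosome relative to the autosomal median, with 1 symbol per ChIP library and no error bars, since each symbol is a single library. Chromosome 7 is highest in all 3 libraries and chromosome 3 lowest, and X lies within the range of autosomes.

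The inputs differed by whole chromosomes. WT input exceeded KO input 1.18-fold on chromosome 19, 1.17-fold on chromosome 14 and 1.14-fold on X, where 167 of 168 bins were higher. It was 0.874-fold on chromosome 12 and 0.884-fold on chromosome 9. The edgeR test called 1983 bins, 908 higher in WT and 1075 lower; with TMM from autosomes 1141 were higher and 991 lower, and without bins of extreme input 905 and 899. The highest were 3 neighbouring bins of vomeronasal receptor genes (chromosome 7, 20000001 to 23000000), the highest of them at log2 0.56 (SE 0.023). The lowest were the chromosome 2 bins with Fmnl2 (53000001 to 54000000, log2 -0.57) and with Upf2 (6000001 to 7000000, -0.37), and the chromosome 8 bin with Defb33 (20000001 to 21000000, -0.35). WT ChIP over KO ChIP carried the same input differences: the bin with Fmnl2 had log2 -0.59 and 2 of the vomeronasal bins 0.50 and 0.48. That comparison called 1651 bins, but 997 with limma-voom, 2 with no dispersion floor and 3 in a quasi-Poisson fit. Its 2 lowest bins, the end of chromosome 12 (log2 -0.77, SE 0.36) and chromosome 9 from 2000001 to 3000000 (-0.60, SE 0.71), had large errors.

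Allelic reads separate the parental genomes. Genome1 had 35.6% of allelic reads on chromosome 1 in WT input and 61.9% in KO input, 58.4% and 30.6% on chromosome 7, and 71.3% and 49.9% on chromosome 19. On X, genome1 had 51.5% in WT input and 46.7% in KO input. ChIP raised this X share by 2.10 and 1.82 percentage points in WT (95% half-widths 0.064 and 0.066) and by 1.99 points in KO (half-width 0.32). The largest autosomal WT shift was 0.271 points, on chromosome 7. KO autosomes shifted as far as X did, by -2.11 points on chromosome 6 and 1.91 on chromosome 7, toward the WT input share on 18 of 19 autosomes. As a median over 156 X bins, the log2 ratio of genome1 to genome2 was 0.11 and 0.084 above input in WT and 0.11 in KO. WT minus KO was -0.015, with a 95% interval of -0.043 to 0.039 from resampled blocks of 10 bins. It was -0.026 without WT replicate 1 and -0.0032 without WT replicate 2. With the WT reads estimated below subtracted from KO ChIP, its sign turned (0.017).

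The allelic edgeR fit called 56 of 156 X bins in WT, all with more genome1 in ChIP, against 36 of 2403 autosomal bins. The highest was the bin from 7000001 to 8000000, which holds 27 protein-coding genes, among them Foxp3, the regulator of regulatory T cells. There genome1 had 55.1% and 54.3% in WT ChIP and 49.5% in WT input (log2 0.30, SE 0.026). Genome1 rose there in KO as well, with 50.7% in ChIP and 46.2% in input (log2 0.26, SE 0.086). WT minus KO in that bin was 0.044 (SE 0.090). In KO the fit called 10 of 156 X bins (6.41%), all with more genome1 in ChIP. It called 96 of 2403 autosomal bins (4.00%), 45 with more genome1 and 51 with less. With no dispersion floor and in a quasi-Poisson fit it called 0 of either. Those fits have the limits given above for WT minus KO, although the deviance was not checked in the allelic fit. WT and KO differed in 1 X bin, from 105000001 to 106000000 with Atrx, a chromatin remodeller; its adjusted p in edgeR was 0.0429, it was named after its value was seen, and it too was lost in both of those fits.

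**Figure D3:**
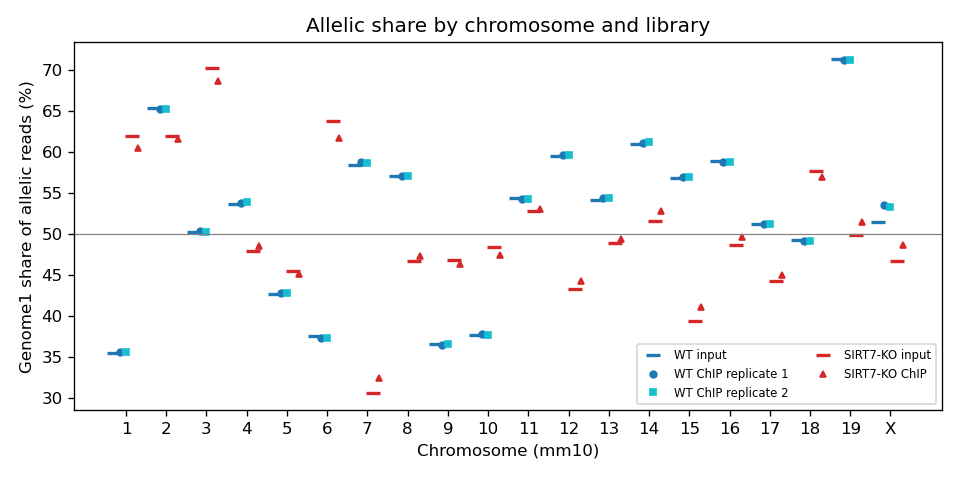
Share of allelic reads from genome1 by mm10 chromosome, with bars for inputs and symbols for ChIP libraries. WT input and ChIP coincide on autosomes, and on X the ChIP share lies above input in both genotypes.

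**Figure D4:**
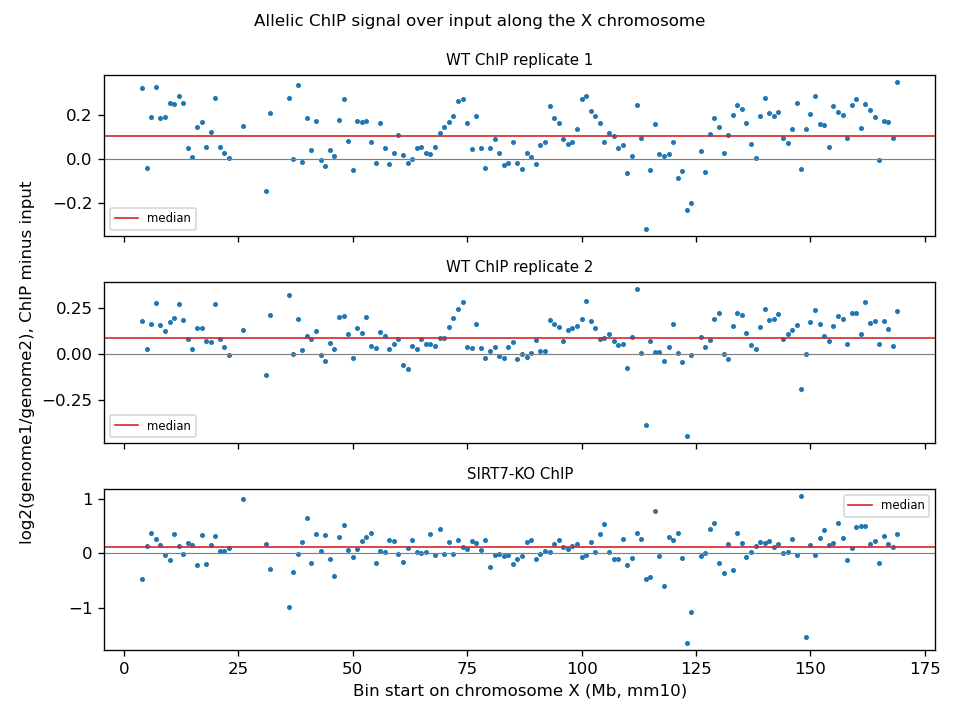
Log2(genome1/genome2) in ChIP minus input for 156 bins along X, 1 panel per ChIP library, with the median as a red line; vertical scales differ between panels because the KO library is shallow. The medians are 0.11 and 0.084 in WT and 0.11 in KO.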

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

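All weighing tests in this part were chosen only after the results were seen. The difference between genotypes was called for 73 bins in the edgeR fit with the dispersion floor, itself set after the calls had been seen. The bins named by rule had WT minus KO values of 0.29 (chromosome 4, 76000001), 0.25 (9, 47000001), 0.24 (7, 40000001), 0.23 (8, 93000001), 0.22 (7, 61000001), 0.22 (7, 71000001), 0.21 (16, 97000001), 0.20 (17, 7000001), 0.20 (1, 125000001) and 0.20 (4, 60000001). The lower ones had -0.22 (1, 24000001), -0.19 (9, 52000001), -0.18 (1, 117000001), -0.16 (18, 34000001), -0.16 (2, 117000001), -0.15 (15, 54000001), -0.15 (5, 123000001), -0.14 (3, 90000001), -0.14 (9, 103000001) and -0.13 (10, 44000001). Most of the bins in both directions lost their call with DESeq2, several with library totals and all with limma-voom. In the allelic fit 51 bins differed between genotypes, 1 of them on X. With no dispersion floor and in a quasi-Poisson fit, both counts were 0. The allelic count rose to 205, 7 of them on X, with a floor 2 times as high, and to 119 autosomal and 4 X bins with a minimum of 100 allelic reads. Chromosome Y, which no comparison used, had 0.118% and 0.120% of reads in WT ChIP and 0.127% in KO ChIP, above 0.112% and 0.108% in the inputs, in cells labelled female.

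In the deposited ratios, WT ChIP over input was 34.6 and 32.96 times KO ChIP over input at the median bin. Read totals alone give 34.2 and 32.9. The fold varied little over most bins, its 95th percentile being 1.17 and 1.15 times its 5th in the WT libraries, as unequal totals would give. Single bins lay farther off, such as the short end bin of chromosome 12, with WT minus KO of -0.61 and -0.65. If the differences between 1 Mb bins in WT came from SIRT7, its loss would flatten the KO profile, but the slope of KO on WT was 0.94. Binding at sites much narrower than a bin could be lost with little change in this slope, so the slope does not address it. A lower ChIP yield from KO cells would give the same single factor and stays open, since no spike-in was analysed here.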

How the results depend on the processing

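The dispersion settings, thinning, robust estimation and the subtraction of estimated WT reads were chosen after seeing the data; the others were fixed before. WT over input (1938 bins) and the inputs (1983) stayed within 1.5 times under each setting but one: WT over input gave 986 after thinning, which lowers depth. KO over input gave 479 with limma-voom, 368 with no dispersion floor and 59 in a quasi-Poisson fit, against 1297. WT over KO ChIP gave 997, 2 and 3 in those fits, against 1651. WT minus KO gave 18 with library totals, 6 with DESeq2, 1 with limma-voom, 3 after thinning, 121 after subtracting estimated WT reads, 0 with no floor, 0 quasi-Poisson, 115 and 279 with floors 1.1 and 2 times as high, against 73. With no floor the edgeR deviance was numerically wrong; a quasi-Poisson fit applies the overdispersion of deep WT libraries to the shallow KO library; the cause of the other changes was not tested. Of 1274 values of named bins, 1135 were the same, 130 lost their call, 3 gained one, 6 moved and 0 reversed. Allelic X calls in KO (10) were 0 with no floor and 0 quasi-Poisson. X WT minus KO moved from 0.0018 to 0.0096 with summed counts and to 0.20 without input, which leaves the input difference in; without extreme-input bins the X values moved to -0.015 and -0.033 in WT and to -0.028 in KO, and the cause was not tested. The KO allelic X median moved to 0.078, and WT minus KO to 0.017, after subtracting estimated WT reads. Leaving out a WT library gave X values of -0.021 to -0.0026, X WT minus KO of -0.0028 to 0.0064, allelic X medians of 0.084 to 0.11 and 6 to 8 lists set apart; no test is possible then, as no residual degree of freedom is left. Without extreme-input bins chromosome 15 had no bin left and gave no value. No paired analysis was possible because only the WT ChIP libraries carry replicate numbers. Depth limits KO values: the self-test called 8% of bins seeded with a WT minus KO change of 0.1.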

Other observations

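All tests in this part were chosen only after the results were seen. On autosomes, allele shares in WT ChIP lay within 0.271 points of WT input, but those in KO ChIP moved away from KO input, by 1.91 points on chromosome 7 and by -2.11 on chromosome 6. The shift pointed toward the WT share on 18 of 19 autosomes. It rose with the mean WT ChIP share minus the KO input share (Pearson's r 0.969, Spearman's rho 0.965, permutation p 1e-05 for each, the smallest they can give). Without chromosomes 6 and 1, r was 0.961. The shift and that difference both contain the KO input share, so an error in it would also raise r. A pull of shallow data toward equal shares is argued against: with both terms in 1 fit, the term for the WT share was 6.65% (5.15 to 8.37) and that for equal shares 1.44% (-1.77 to 3.86). An effect of SIRT7 loss alone would not follow the WT shares, and the permutation p of 1e-05 argues against it as the whole cause. A candidate explanation is that 7.32% (6.49 to 8.24) of KO ChIP reads came from WT libraries or cells, about 363200 reads or 0.107% of the WT ChIP reads. Chromosome copy number gave 7.15% (4.63 to 10.1), but its counts include the allelic reads. Unassigned reads alone gave 6.08% (1.4996 to 10.1), with r of 0.613 over chromosomes. Both of these slopes relate WT over KO input to a difference that itself contains WT over KO input. An error in either single input would raise them with no WT reads present, so they cannot decide the question.

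The rise of genome1 on X in ChIP was present in both genotypes. SIRT7 binding to the genome1 X is argued against as the whole cause: after removal of the estimated WT reads the KO shift was 1.62 points (1.27 to 1.962, counting error only), 82.6% of the WT shift, while the largest left on an autosome was -0.717, on chromosome 2. Reads from WT libraries are argued against as the source of the KO shift, since they would have to make up 29.6% of the KO ChIP reads, against the 7.32% (6.49 to 8.24) estimated from autosomes. ChIP background that is higher in gene-rich chromatin of one X may account for part of it. X bins at or above the median of 4 genes exceeded the others by 2.23 and 1.71 points in WT and by 1.19 (half-width 0.651, counting error only) in KO. The other X bins still shifted by 0.73 and 0.78 points in WT and by 1.26 in KO, with no WT reads removed. Those bins hold fewer than 4 genes but are not all free of genes, so this split cannot tell whether gene number covers that part. Bin by bin, Spearman's rho of gene number with the shift was 0.592 and 0.544 in WT but 0.124 in KO. Counting error in the shallow KO library would lower its rho, and WT libraries were not thinned to that depth for it. The values therefore do not tell whether the relation is weaker in KO, and a smaller SIRT7-dependent part stays open.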
